A study of Danio rerio with 6 samples.

How the data were processed

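The material was total RNA from zebrafish (Danio rerio), sequenced as small RNA libraries. The labels give 6 libraries, 1 for each combination of genotype (tdrd6a heterozygote or tdrd6a mutant) and material (early oocytes, late oocytes or whole ovary), and the oocytes had been selected by size. Each library was assigned to its group from its sample description, and every library name in the deposited table equalled the description of 1 sample. The descriptions mark every library as input, and only those of whole ovary also as adult. The labels do not say whether libraries come from separate fish, so every p-value below measures only the spread between these libraries. That spread may be technical, and with 1 library per group it also holds any genotype effect that differs between materials.

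Per the file headers, the table deposited by the authors has 1 line per read and annotated repeat element, with the element's class, superfamily, family name, position and strand, the read's length in nt, its orientation to the element and the library name. It has no column of counts, so reads per family were obtained here by counting lines. It joins 2 tables, each under its own header line: 1 of the 2 ovary libraries, whose longest read is 35 nt, and 1 of the 4 oocyte libraries, whose longest read is 39 nt. The shortest read in the table is 15 nt. Per the submitters' processing notes, cutadapt, Bowtie 0.12.8, bedtools 2.25.0 and the genome build Zv9 were used. Their settings, and the treatment of reads that map to several places, are not given in the sources used here. Whether families with near-identical copies share reads is therefore unknown, and 73359 of 814122 annotated copies with reads (9.01%) overlapped another one, so values of single copies are uncertain. Element positions follow the half-open convention that counts from 0, since 63741 neighbouring copies abut under it and 10725 under the closed one, and positions are printed here counted from 1. No genome or annotation of Zv9 was used here, so the genes around single copies were not analysed. The tdrd6a transcript is not measured by transposon reads, so the genotype labels have no check in the data.

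The 45306496 lines covered 960 families in 4 classes (LTR, LINE, DNA and SINE) and 53 superfamily names, and 25 families carried 2 superfamily names, of which the one with more reads was kept. Levels are given as CPM, reads per 1000000 transposon reads of the library, since reads elsewhere in the genome were not analysed here. A change in the total of transposon small RNA between libraries is therefore not measured, and every difference is relative to the other families. Depth ranged from 1302475 reads (mutant whole ovary) to 11327494 reads (heterozygote early oocytes). A family without reads was given a floor of 3 reads, between 0.265 and 2.30 CPM. Shares of a library have exact Clopper-Pearson 95% intervals, and ratios of 2 libraries have exact conditional binomial 95% intervals. These ratios and intervals are of CPM before the scaling described below. Log2 ratios of families, counts of families past a fold and the ranking of families use scaled values. Intervals and floors cover counting error only, since reads were not counted by molecular identifiers.

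The planned analysis was a negative binomial test of counts. As the table holds no count column, the planned fallback for other units was used: limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with the trimmed mean of M values for scaling (30% of ratios and 5% of levels trimmed at each end) and moderated variances with a trend on abundance. On this scale the change of rare families is understated. Families needed at least 10 reads, scaled to the median depth, in 3 libraries and 15 reads in all, which left 953. A negative binomial quasi-likelihood test of the tallied reads was added as an alternative after the data had been examined, with MASS 7.3.60.0.1, 1 dispersion for all families (0.0131 for genotype and for stage) and quasi-dispersions moderated by limma. Genotype was fitted with material as a block (3 pairs, 2 residual degrees of freedom), and late against early oocytes in the same fit over both genotypes. Adjusted p-values are Benjamini-Hochberg values over the 953 families, with a threshold of 0.05. Within a single material or genotype there is 1 library per group, hence no replicate check and no p-value. Shares of classes and strands over whole libraries were compared without a test, and an exact permutation test of 3 pairs has a smallest two-sided p of 0.25.

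Superfamily lists were fixed before the data were examined, and families were placed by the superfamily the table gives: LTR ERV, Gypsy, DIRS, Ngaro, Pao and Copia, LINE L1, L2, I, Rex-Babar and RTE, DNA hAT, TcMar, En-Spm, PiggyBac, Harbinger, Kolobok and Maverick, RC Helitron, and SINE. These 20 lists held 815 families, and 145 families fell in none. A few family names differ from their superfamily: Copia6-LTR_DR and Copia-8-LTR_DR are counted under Gypsy, and CR1-16_DR under Rex-Babar. Planned lists for R2, Penelope, Merlin and Crypton elements and for structural RNA had no family among those counted here. Lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 20 lists.

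Families named in the text follow a rule that was also fixed before the data were examined. Eligible families had a mean of at least 100 CPM over the 6 libraries (750 families with 99.2% of reads). For genotype and for stage, up to 10 families per direction past the threshold with the same sign in every pair were to be named, filled to 5 per direction by the largest smallest absolute log2 ratio where fewer passed. Within each material the 5 highest and 5 lowest ratios were named, and the 10 most abundant families over all libraries. This gave 49 families, and any other family or copy named was chosen after its values were seen. The comparison of whole ovary with oocytes, the interaction of genotype with whole ovary, the strand balance per family, and the comparison of single copies were all added after the data had been examined. Strand balance was tested with limma on the log2 ratio of antisense to sense reads, with 1 read added to each, over 735 families.

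The fit was tested on simulated counts for the real families and depths. In these counts a genotype change had the same size in all 3 materials, and for stage only the late oocytes differed from a common level. The recovered shares therefore do not hold for families whose genotype ratio differs between materials. A count of 0 families in the real data does not show that few families change. With a dispersion of 0.005, 99.0% of 99 families changed 1.5-fold and 100 of 100 changed 2-fold by genotype were recovered, and 4 of 753 unchanged families were called. With a dispersion of 0.02, the shares by genotype were 72% of 100 families at 1.5-fold and 99.0% of 99 at 2-fold, with 5 of 752 unchanged families called. For late against early oocytes, 98% at 1.5-fold and 95% at 2-fold were recovered at a dispersion of 0.005, and 46% and 96% at 0.02. The negative binomial test recovered 97.98% of 99 families changed 1.5-fold by genotype at a dispersion of 0.005 and 76% of 100 at 0.02, with 3 of 753 and 5 of 752 unchanged families called. For late against early oocytes it recovered 100% of 100 and 50% of 100, with 10 of 752 and 10 of 753 called.

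Alternatives covered median-ratio and total-count scaling, no filter and a filter of 100 reads, antisense or sense reads only, reads of 24 to 32 nt only, each pair left out in turn and no material term. Chosen after seeing the data were pseudocounts of 0.1 and 10 CPM, voom weights, a fit without the variance trend, the negative binomial test, each list without the family that changed most in summed CPM, antisense shares of lists without each family in turn, and settings for the added comparisons. Nucleotide composition, overlap of read ends, distinct sequences and weights for multiple hits could not be computed, since the table gives neither sequences, nor positions nor identifiers of reads. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and mawk 1.3.4, and plots with matplotlib 3.10.9.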

Results

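Small RNA was profiled in ovaries and oocytes of zebrafish that were heterozygous or mutant for tdrd6a, which encodes a germ granule protein with several Tudor domains. The title of the series places Tdrd6a between piRNAs bound by Ziwi, a zebrafish Piwi protein, and the delivery of germ plasm mRNAs to primordial germ cells. piRNAs are the small RNAs that guide Piwi proteins to transposon transcripts, and the reads analysed here are those on annotated transposons. Early oocytes, late oocytes and whole ovary were each represented by 1 heterozygote and 1 mutant library. Early oocytes gave 11327494 reads in the heterozygote and 11048083 in the mutant, late oocytes 9265436 and 8470835, and whole ovary 3892173 and 1302475. The whole ovary libraries, and the mutant one above all, therefore have the widest counting error.

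In all 6 libraries the transposon reads had the length of piRNAs. The most frequent length was 29 nt in the 4 oocyte libraries and 28 nt in both ovary libraries, and reads of 24 to 32 nt made up 95.8% of reads in heterozygote and mutant early oocytes, 96.7% and 96.2% in late oocytes, and 91.7% and 93.9% in whole ovary. The mean length of mutant reads differed from that of heterozygote reads by −0.0681 nt in early oocytes, 0.208 nt in late oocytes and 0.254 nt in whole ovary, so the direction was not shared by the 3 materials.

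**Figure D1:**
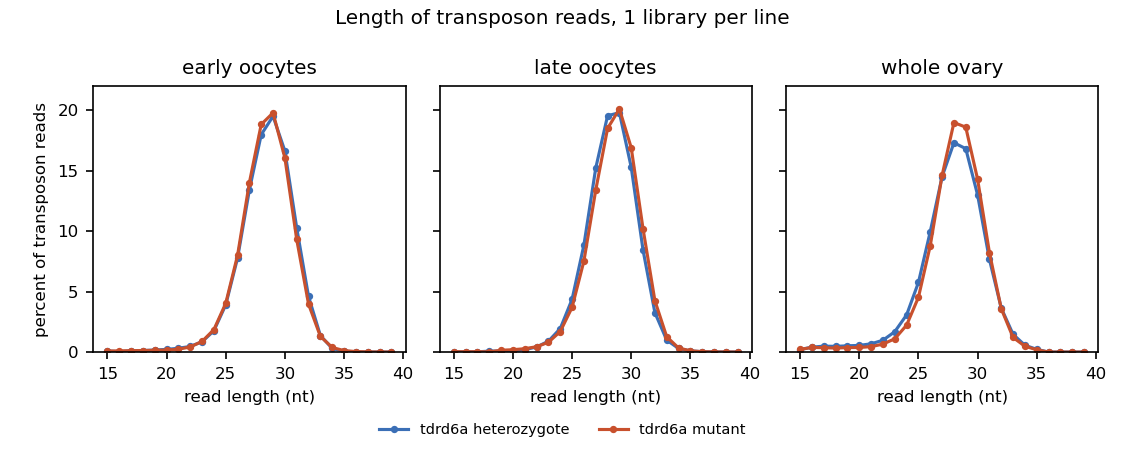
Length of transposon reads in nt (x axis) against the percent of the library's transposon reads (y axis), with 1 line per library, blue for tdrd6a heterozygote and red for tdrd6a mutant. Both genotypes peak at 29 nt in early and late oocytes and at 28 nt in whole ovary.

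LTR retrotransposons, which move through an RNA copy flanked by long terminal repeats, took most of the reads in every library. Their share was 64.0% in heterozygote and 61.5% in mutant early oocytes, 64.4% and 62.4% in late oocytes, and 59.8% and 58.9% in whole ovary, lower in the mutant in each of the 3 pairs. LINE retrotransposons, which lack such repeats, were higher in the mutant in each pair, at 12.9% and 13.4%, 12.5% and 13.2%, and 13.3% and 14.2%. DNA transposons, which move by excision, were at 22.9% and 24.9% in early oocytes and 22.7% and 24.1% in late oocytes, with 26.7% in both ovary libraries. The short SINE elements held between 0.216% and 0.405% of reads. The widest exact binomial interval of an LTR share, in the mutant ovary, ran from 58.8% to 59.0%. Class shares were not tested, and an exact permutation test over 3 pairs has a smallest two-sided p of 0.25.

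The most abundant family was LTR1_DR in every library, with 2.88% and 2.31% of reads in heterozygote and mutant early oocytes, 2.84% and 2.57% in late oocytes, and 2.56% and 2.43% in whole ovary. Next came Polinton-1_DR, a large self-synthesising DNA element, the retrotransposon BHIKHARI-5-I_DR-int, Gypsy101-I_DR-int, DIRS-2_DR, Polinton-2_DR, DIRS-3_DR, Copia6-LTR_DR, Gypsy5-I_DR-int and DNA9TA1_DR. Of these 10 families, DNA9TA1_DR, a Tc1-type element, had the largest genotype ratio in early oocytes and whole ovary: 6345 and 11049 CPM (reads per 1000000 transposon reads of the library) in heterozygote and mutant early oocytes, 9358 and 11950 in late oocytes, and 4763 and 13181 in whole ovary. Its log2 difference over the 3 pairs was 0.93 ± 0.26 (SE) with a Benjamini-Hochberg adjusted p of 0.157 from limma. The 10 most abundant families of each library held between 13.8% and 15.2% of reads.

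The genotype comparison asked whether the small RNA of any family differs between tdrd6a mutant and heterozygote in the same direction in early oocytes, late oocytes and whole ovary. Among families higher in all 3 mutant libraries, BEL5-LTR_DR, a Pao-type retrotransposon, had 120 CPM in heterozygote and 390 in mutant early oocytes, 127 and 439 in late oocytes, and 330 and 454 in whole ovary, a log2 difference of 1.37 ± 0.26 (SE, n = 3 pairs). Gypsy40-I_DR-int was at 3191 and 4982, 3618 and 5123, and 2071 and 3053 CPM in the same order (0.62 ± 0.09), and Copia3-I_DR-int at 456 and 650, 328 and 541, and 391 and 740 (0.77 ± 0.14). ERV1-N3-LTR_DR (0.58 ± 0.09) and CR1-16_DR (0.69 ± 0.11) were also higher in each pair. In the other direction, the DNA transposon Tc1-7_DR had 652 and 288, 937 and 329, and 705 and 291 CPM (−1.26 ± 0.12). Gypsy65-I_DR-int (−0.87 ± 0.14), Gypsy11-LTR_DR (−0.74 ± 0.12), Gypsy100-I_DR-int (−0.72 ± 0.10) and TDR13B (−0.66 ± 0.10) were lower in each pair.

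None of these 10 families passed the threshold over the 3 materials, each with an adjusted p of 0.111. With limma and Benjamini-Hochberg adjustment, 0 of 953 families passed, 201 had an unadjusted p under 0.05, and the smallest adjusted p was 0.111. A negative binomial test of the tallied reads also called 0, with 206 at an unadjusted p under 0.05. The genotype difference had the same sign in all 3 pairs for 420 families, 195 higher and 225 lower, which is 44.1%, against 25% for independent pairs. Early and late oocytes are not independent in this respect, with the same sign for 75.8% of families, and 37.9% would be alike in all 3 pairs if the whole ovary signs were unrelated to those in oocytes. Without the whole ovary pair, 225 families passed (120 higher and 105 lower, 1 residual degree of freedom), all 10 families above among them, while 0 passed without the early or without the late oocyte pair. The 10 had been chosen for large ratios of 1 sign in all 3 pairs, so their passing here follows in part from that choice. Of these 225, 130 (57.8%) had the same direction in whole ovary. That share is not above the 58% of the 750 eligible families whose mean oocyte ratio and whole ovary ratio had the same sign. The difference of Gypsy100-I_DR-int was 0.24 in log2 on sense reads alone.

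**Figure D2:**
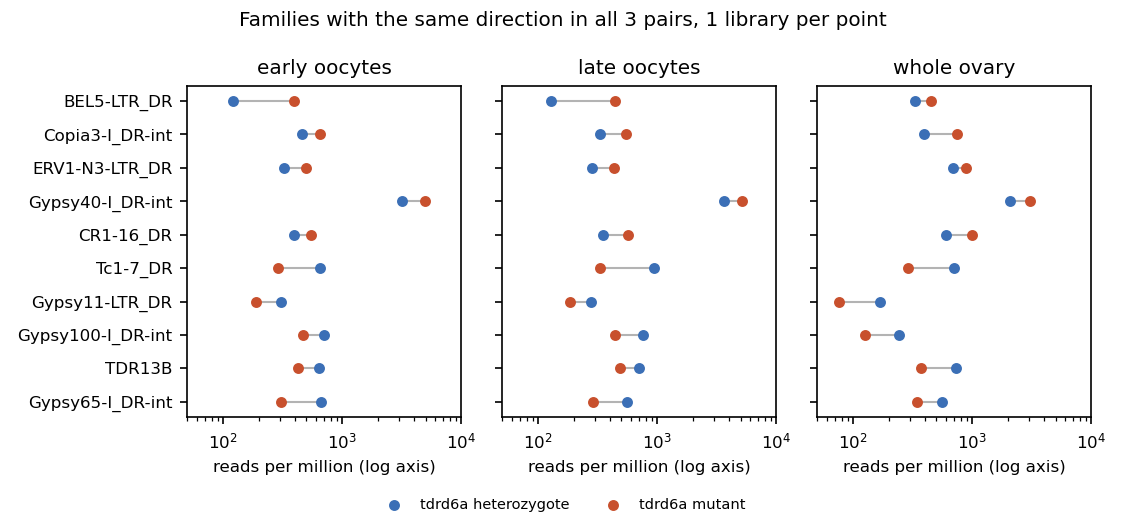
CPM on a log axis (x axis) of the 10 families named for genotype (y axis), with blue points for the tdrd6a heterozygote library and red points for the mutant library of each material. Tc1-7_DR went from 652 to 288 in early oocytes, 937 to 329 in late oocytes and 705 to 291 in whole ovary, and none of the families passed the test over the 3 materials.

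Endogenous retroviruses (LTR ERV) were higher in the mutant with camera in limma at the preset correlation (Benjamini-Hochberg adjusted p = 0.000599), a call that was lost with an estimated correlation (adjusted p = 0.805). Of 39 ERV families tested, 20 (51.3%) were higher in all 3 mutant libraries and 2 (5.13%) were lower, against 20.5% and 23.6% of all families. If the whole ovary signs of the list were unrelated to those in oocytes, 49.3% and 3.55% would be so. The list had a median log2 difference of 0.18, and none of its families passed alone. Summed over the list, the mutant level was 1.21 times that of the heterozygote in early oocytes, 1.14 times in late oocytes and 0.992 times in whole ovary. These sums depended on ERV1_DR-I-int, without which they were 1.09, 1.04 and 1.08 times, with a camera adjusted p of 0.000542. The LINE L1 list was also higher, with a camera adjusted p of 0.0220, and an adjusted p of 0.805 with an estimated correlation. Of its 18 families, 8 (44.4%) were higher in all 3 pairs, among them L1-7_DR at a log2 difference of 0.44 ± 0.08 (adjusted p = 0.111), and 1 was lower. That share is not above the 46.3% for whole ovary signs unrelated to those in oocytes. The genotype difference of the LINE L1 list no longer passed without the late oocyte pair (adjusted p = 0.0817), without the whole ovary pair (0.129), on antisense reads (0.0849), on sense reads (0.05002) or without L1-7_DR (0.0669).

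No other list passed, with camera adjusted p between 0.139 and 0.9998. The largest list, LTR Gypsy, had 70 of 315 families higher and 70 lower in all 3 pairs. The corresponding counts were 10 and 18 of 75 for LTR Pao, 1 and 6 of 16 for LTR Ngaro, 1 and 1 of 7 for LTR DIRS, and 2 and 1 of 8 for LTR Copia. Among LINE lists they were 6 and 6 of 29 for L2, 5 and 1 of 14 for Rex-Babar, 1 and 2 of 4 for RTE, and 1 and 1 of 4 for I. Among DNA transposons they were 16 and 38 of 143 for hAT, 9 and 14 of 38 for TcMar, 12 and 1 of 29 for En-Spm, 3 and 7 of 22 for Harbinger, 1 and 8 of 18 for Kolobok, 2 and 4 of 13 for PiggyBac, 1 and 0 of 4 for Maverick, and 2 and 1 of 5 for Helitron. SINE had 0 higher and 2 lower of 7. Adjusted over the list alone, 6 En-Spm, 2 Kolobok, 2 Copia, 1 TcMar, 1 Rex-Babar and 1 DIRS family passed, and 0 in each of the other lists. The median, the mean and the camera direction differed in sign for LTR Copia, LTR Gypsy and LINE L2.

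Without the whole ovary pair, in the 4 oocyte libraries, the families that passed lay in most lists. LTR Gypsy had 48 that rose and 37 that fell in the mutant of 315, LTR ERV 10 and 1 of 39, LTR Pao 8 and 14 of 75, LTR DIRS 0 and 4 of 7, and LTR Ngaro 0 and 4 of 16. DNA TcMar had 2 that rose and 8 that fell of 38, En-Spm 7 and 3 of 29, LINE Rex-Babar 6 and 2 of 14, and LINE L1 4 and 0 of 18. In this fit ERV1_DR-I-int rose by 1.55 ± 0.08 (SE) in log2, with a limma Benjamini-Hochberg adjusted p of 0.00327, and BEL17-LTR_DR fell by 3.05 ± 0.09 with an adjusted p of 0.00106. In whole ovary the mutant ratio of ERV1_DR-I-int was 0.218 and that of BEL17-LTR_DR 0.663. The fit takes early and late oocytes of a genotype as repeats of each other, and whether they come from separate fish is not stated. Its p-values therefore measure how alike the 2 oocyte pairs are, not the spread between fish of a genotype. Only 24 of the 225 families changed by more than 2-fold.

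Within single materials, most families differed little between genotypes. Of 750 families, 90.0% were within 1.5-fold in early oocytes, 88.3% in late oocytes and 87.2% in whole ovary, and 14, 11 and 32 families differed by more than 2-fold. In early and late oocytes the highest mutant ratios belonged to BEL5-LTR_DR (3.25-fold, 95% interval 3.05 to 3.45, and 3.45-fold, 3.23 to 3.69), ERV1_DR-I-int (3.04 and 2.80) and Gypsy121-LTR_DR (2.96 and 2.73). DNA-10-1_DR (2.49) and piggyBac-N2_DR (2.08) followed in early oocytes, and Gypsy55-I_DR-int (2.33) and Gypsy142-LTR_DR (2.32) in late oocytes. The lowest ratio was that of BEL17-LTR_DR, with 214 CPM in heterozygote and 23.4 in mutant early oocytes and 224 and 27.9 in late oocytes. Copia4-I_DR-int (ratios of 0.302 and 0.340), BEL2-I_DR-int (0.418 and 0.371) and Tc1-7_DR (0.442 and 0.352) were also low in both, with Gypsy153-I_DR-int at 0.401 in early and DNA8-6_DR at 0.432 in late oocytes.

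In whole ovary other families stood at the ends of the range. DNA-2-8_DR, an En-Spm element, was 3.13-fold higher in the mutant (95% interval 3.003 to 3.264), followed by Gypsy-22-LTR_DR (2.998), DNA9TA1_DR (2.77), Gypsy-24-LTR_DR (2.61) and BELPADRE_I-int (2.51). These ratios are before scaling, and the scaled log2 ratio of DNA-2-8_DR was 1.81. Gypsy-18-I_DR-int had 273 reads in the heterozygote and 0 in the mutant, at least 30.5-fold lower against the floor of 3 reads in the mutant library. The exact conditional 95% interval of this ratio, which also covers the counting error of the heterozygote, reached up to 0.0407. Gypsy-18-I_DR-int was not low in oocytes, where it had 507 and 434 CPM in heterozygote and mutant early oocytes. Gypsy75-I_DR-int had 246 and 7 reads (ratio 0.085, interval 0.034 to 0.178), Gypsy142-I_DR-int 6794 and 457 (0.201), and CR1-12_DR 752 and 53 (0.211). ERV1_DR-I-int was at 6633 and 1449 CPM, a ratio of 0.218 in whole ovary against 3.04 and 2.80 in oocytes.

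Across the 750 families, the log2 genotype ratios of early and late oocytes had a Pearson r of 0.827 and a Spearman rho of 0.7498. Those of whole ovary had an r of 0.139 (rho 0.237) with early and 0.0959 (rho 0.181) with late oocytes. These 3 correlations are across families, which are not independent replicates. Between early and late oocytes, 11 families (1.47%) had genotype ratios more than 1.5-fold apart and 2 more than 2-fold apart, the largest being DNA-2-30_DR at a log2 difference of 1.28, early minus late. The genotype effect in early against late oocytes was not tested, since 4 libraries leave no degree of freedom for it.

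**Figure D3:**
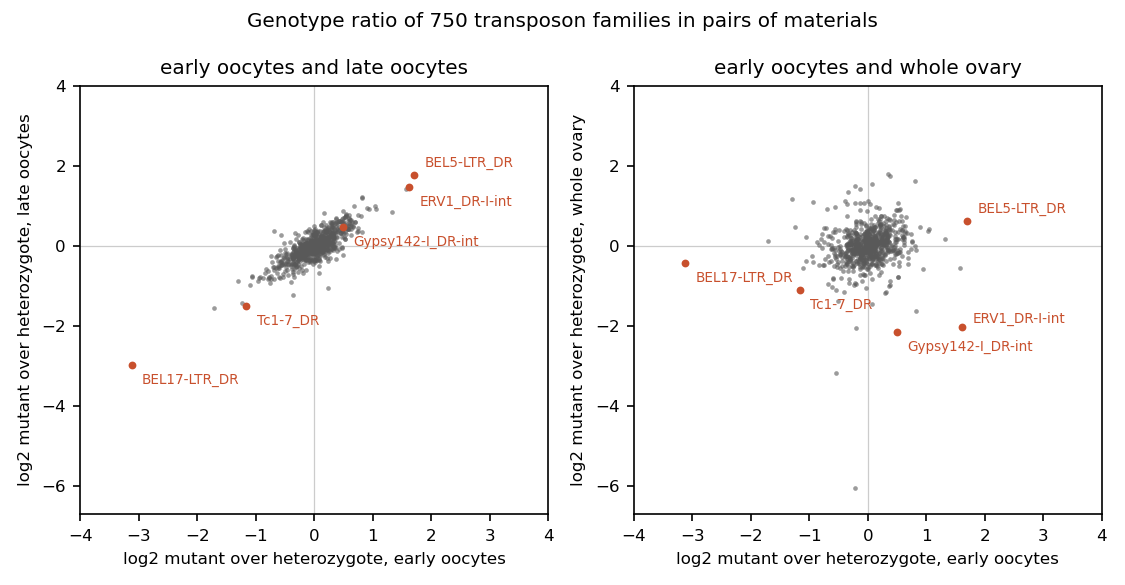
Log2 ratio of mutant over heterozygote for 750 families in early oocytes (x axes) against late oocytes (left y axis) and whole ovary (right y axis), with 1 point per family and 5 named families in red. The points follow the diagonal for the oocyte pairs (Pearson r 0.827 across families) and not for whole ovary (0.139), where ERV1_DR-I-int changes sides.

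The strand of the reads was compared because zebrafish Ziwi is loaded mostly with antisense piRNAs and the other Piwi protein, Zili, mostly with sense ones. Antisense reads made up 70.8% of transposon reads in heterozygote and 66.3% in mutant early oocytes, 68.3% and 65.8% in late oocytes, and 70.4% and 67.9% in whole ovary, where the exact interval of the mutant ran from 67.8% to 68.0%. The mutant share was thus different by −4.48, −2.46 and −2.56 percentage points, lower in each of the 3 pairs. Smaller differences were found as the median over families of at least 100 reads (−2.52, −0.374 and −0.675 points), as the median change of the 750 families (−1.51, −0.524 and −1.07) and with each family's share of reads held at the mean of the pair (−2.40, −1.28 and −1.43). Among reads of 24 to 32 nt the differences were −4.51, −2.47 and −2.47 points. LTR reads were less antisense in each mutant library (−4.31, −1.94 and −3.35 points) and DNA transposon reads likewise (−3.58, −1.77 and −2.03), whereas LINE reads differed by −3.33, −3.60 and 0.119 points. With 3 pairs the smallest exact two-sided p is 0.25. Libraries of 1 genotype differed as well. Late minus early oocytes, the antisense share of all reads differed by −2.49 points in the heterozygote and −0.476 in the mutant. The heterozygote value is close in size to the genotype differences in late oocytes and whole ovary.

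Among the 20 lists, 6 (30%) had a lower antisense share in all 3 mutant libraries and 2 (10%) a higher one. This is close to the 33% and 9% for whole ovary signs unrelated to those in oocytes, since early and late oocytes had the same sign for 80% of lists. The lower lists were DNA TcMar (−11.7, −8.69 and −15.2 points in early oocytes, late oocytes and whole ovary), LTR Gypsy (−5.54, −1.90 and −4.85), LTR Ngaro (−3.46, −1.56 and −6.80), LINE L2 (−3.46, −3.26 and −3.52), LINE Rex-Babar (−5.77, −4.72 and −1.38) and LTR Copia (−1.99, −1.74 and −3.76). DNA Maverick, the Polinton group, went from 32.03% to 21.42% in early and from 32.5% to 22.4% in late oocytes but from 25.1% to 26.8% in whole ovary. The higher lists were DNA hAT (0.285, 0.686 and 1.31 points) and SINE (2.19, 1.95 and 0.774). These sums also move with the abundance of single families. DNA9TA1_DR, under 7% antisense in each library, took a larger part of TcMar reads in each mutant library, and without it the TcMar differences were −8.38, −7.49 and −8.97 points. With each family left out in turn, the direction stayed shared by the 3 pairs for TcMar, Gypsy and Ngaro, while 1 family ended it for LINE L2 (0.957, 0.375 and −5.61 without CR1-1_DR), LINE Rex-Babar (−6.58, −5.17 and 0.825 without CR1-23_DR), LTR Copia (−0.479, 0.350 and −0.241 without Copia1-I_DR-int), DNA hAT (−0.601, −0.0110 and 0.385 without hAT-N76_DR) and SINE (−0.535, 3.54 and −0.992 without HE1_DR1).

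The strand balance passed the test for 3 of 735 families, all internal parts of Gypsy elements that became less antisense in the mutant. The antisense share of Gypsy87-I_DR-int went from 29.6% to 9.86% in early oocytes, from 26.4% to 10.6% in late oocytes and from 37.7% to 18.6% in whole ovary, and its log2 ratio of antisense to sense reads fell by 1.65 ± 0.17 (SE). Gypsy42-I_DR-int went from 49.2% to 20.6%, 39.2% to 16.3% and 61.6% to 40.6% (−1.62 ± 0.18), and Gypsy116-I_DR-int from 52.3% to 33.0%, 53.7% to 31.9% and 86.3% to 72.7% (−1.23 ± 0.14). Each had a limma Benjamini-Hochberg adjusted p of 0.0277, and 141 families had an unadjusted p under 0.05. In all 3 pairs, 245 families (33.3%) were less antisense in the mutant and 88 (12.0%) more so. Early and late oocytes had the same sign for 71.8% of families, so these shares would be 29.3% and 9.37% if the whole ovary signs were unrelated to those in oocytes. Without the early oocyte pair 0 families passed, and 66 passed without the whole ovary pair, 46 of them less antisense in the mutant.

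**Figure D4:**
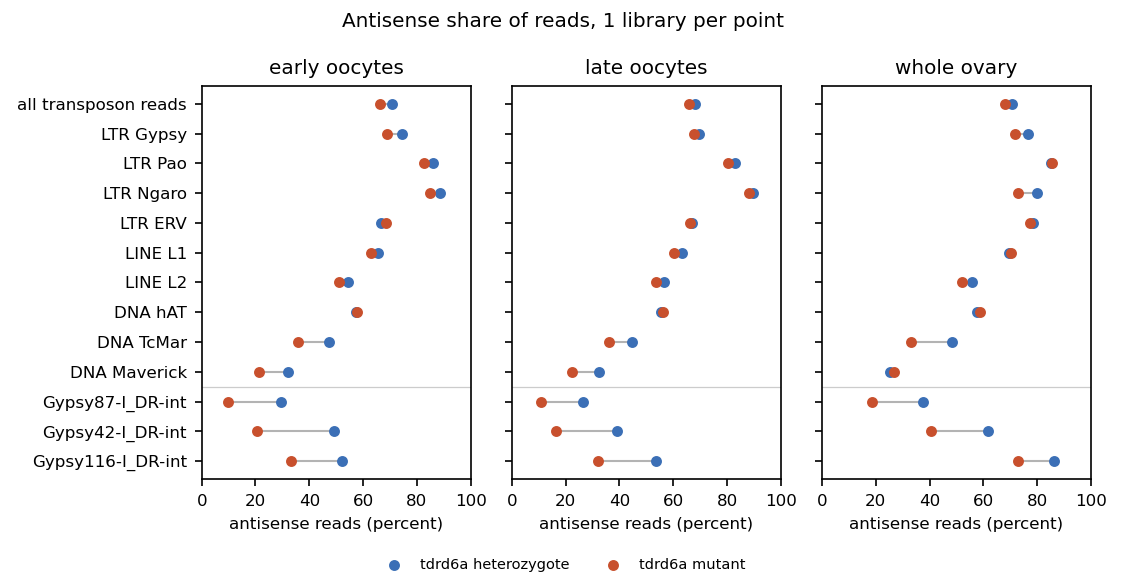
Percent of reads antisense to the element (x axes) for all transposon reads, 9 superfamily lists and 3 Gypsy families (y axis), with blue points for the tdrd6a heterozygote library and red points for the mutant library of each material. The mutant point lies left of the heterozygote point for all reads and for the 3 Gypsy families in each material, with Gypsy87-I_DR-int going from 29.6% to 9.86% in early oocytes.

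The stage comparison asked which families differ between late and early oocytes in both genotypes. Among the families named by the rule, SINE2-1_DR, a tRNA-derived element, differed most, with 722 CPM in early and 1912 in late heterozygote oocytes (2.65-fold) and 752 and 1542 in mutant oocytes (2.05-fold). Its log2 difference over the 2 genotypes was 1.24 ± 0.14 (SE), which did not pass (limma, Benjamini-Hochberg adjusted p = 0.486). The SEs and p-values for stage come from the fit of all 6 libraries. They therefore also hold how far the whole ovary pair departs from the oocyte pairs, and do not measure the spread between 2 genotypes. DNA-2-24_DR, for example, differed by −0.390 in the heterozygote and −0.371 in the mutant in log2, with an SE of 0.21. Gypsy37-LTR_DR (0.73 ± 0.22), Copia-8-LTR_DR (0.51 ± 0.12), EnSpm-N7_DR (0.40 ± 0.17) and DIRS-1B-LTR_DR (0.38 ± 0.10) were higher in late oocytes of both genotypes. DNA-6-N7_DR (−0.43 ± 0.12), DNA-2-24_DR (−0.38 ± 0.21), hAT-N32_DR (−0.38 ± 0.14), CR1-42_DR (−0.35 ± 0.21) and Gypsy-30-I_DR-int (−0.33 ± 0.18) were lower, each with an adjusted p of 0.978. The direction turned for hAT-N32_DR on antisense reads (0.14) and for DNA-6-N7_DR among reads of 24 to 32 nt (0.034).

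For stage, limma called 0 of 953 families, with 24 at an unadjusted p under 0.05. A negative binomial test of the tallied reads called 0 with 32, and limma 0 with 144 at an unadjusted p under 0.05 in a fit of the 4 oocyte libraries alone. The sign was the same in both genotypes for 647 families, 318 higher and 329 lower in late oocytes, against 50% by chance. Of the 750 families, 3 differed by more than 2-fold between late and early oocytes in the heterozygote and 1 in the mutant. The log2 ratios of the 2 genotypes had a Pearson r of 0.517 and a Spearman rho of 0.510 across families, which are not independent replicates. The antisense share of all transposon reads differed by −2.49 points in the heterozygote and −0.476 points in the mutant, late minus early.

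Ngaro retrotransposons, relatives of DIRS elements, were higher in late oocytes as a group. All 16 tested families were higher in both genotypes, against 318 of all 953 families. The list rose 1.16-fold in both, from 52246 to 60372 CPM in the heterozygote and from 46966 to 54379 in the mutant. The LTR Ngaro list passed with camera in limma (Benjamini-Hochberg adjusted p = 9.06e-10), with an adjusted p of 0.526 with an estimated correlation. The SINE list was at 1.57 and 1.32 times the early level (adjusted p = 0.0458), with 3 of 7 families higher in both genotypes and 0 lower. SINE2-1_DR was the 1 SINE family that passed adjusted over the list alone, and without it the list was at 1.15 and 1.02 times the early level (adjusted p = 0.295). LTR Pao fell to 0.900 and 0.951 of the early level, with 43 of 75 families lower in both genotypes and 11 higher (adjusted p = 0.00208), and LTR Copia fell to 0.757 and 0.882, with 5 of 8 lower and 1 higher (adjusted p = 0.0458). The SINE, Pao and Copia lists each had an adjusted p of 0.526 with an estimated correlation. On sense reads alone none of these 4 lists passed, each with an adjusted p of 0.0957 except LTR Copia at 0.561, and Ngaro and Pao changed direction. The SINE list also missed the threshold on antisense reads (0.0764), without a filter (0.0894) and in the stage fit of the 4 oocyte libraries (0.118), and LTR Copia without a filter (0.0615), with median-ratio scaling (0.0651) and without Copia1-I_DR-int (0.117).

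No other list passed for stage, with camera adjusted p between 0.0681 and 0.924 and 0 families passing when adjusted over the list alone, although DNA hAT had an adjusted p of 0.0476 without HAT1_DR. DNA hAT had 66 of 143 families higher in late oocytes of both genotypes and 30 lower, LTR Gypsy 91 and 119 of 315, LTR ERV 15 and 9 of 39, LTR DIRS 4 and 2 of 7, and DNA TcMar 20 and 11 of 38. The counts were 2 and 18 of 29 for En-Spm, 8 and 5 of 22 for Harbinger, 4 and 5 of 18 for Kolobok, 9 and 2 of 13 for PiggyBac, 0 and 2 of 4 for Maverick, and 3 and 1 of 5 for Helitron. LINE lists had 3 and 10 of 18 for L1, 6 and 13 of 29 for L2, 2 and 9 of 14 for Rex-Babar, 1 and 2 of 4 for RTE, and 0 and 2 of 4 for I. Only for RTE did the median, at −0.04 in log2, and the camera direction differ in sign.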

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

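The test of the difference itself, the tests on a common slope and on single copies were all chosen after the result was seen, and the test on depth was fixed before. The genotype ratio differed between whole ovary and oocytes for 102 of 953 families by the interaction term in limma (Benjamini-Hochberg adjusted p under the threshold, 41 higher and 61 lower in whole ovary, 1 residual degree of freedom), and 320 families had an unadjusted p under 0.05. The term takes early and late oocytes of a genotype as repeats of each other. With 1 ovary library per genotype the spread of ovary libraries was not measured, and the calls assume that it equals the spread between early and late oocytes. With total-count scaling 213 families passed, 45 higher and 168 lower, as the median over all families shifted from −0.02 to −0.18 in log2. The count was 44 with voom weights and 49 with a negative binomial test of the tallied reads.

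Of the 49 families named by the rule, 18 were among those called, against 102 of all 953 families. Part of the 49 were named for an extreme ratio within 1 material, which by itself raises this share. No superfamily list passed for this term with camera. The families with a lower mutant ratio in whole ovary than in oocytes were of several kinds: the difference in log2 was −3.58 for ERV1_DR-I-int, −2.64 for Gypsy142-LTR_DR, −2.63 for Gypsy142-I_DR-int, −2.56 for Gypsy75-I_DR-int, −2.05 for Gypsy121-LTR_DR and −1.11 for Gypsy55-I_DR-int. The fitted value of −5.90 for Gypsy-18-I_DR-int rests on 0 reads in the mutant ovary and depends on the pseudocount. BEL5-LTR_DR (−1.12) and the LINE elements CR1-12_DR (−1.96) and CR1-42_DR (−0.68) were also lower. The 8 families with a higher mutant ratio in whole ovary were BEL17-LTR_DR (2.62), BEL2-I_DR-int (1.82), BELPADRE_I-int (1.59), Gypsy153-I_DR-int (2.26), Copia4-I_DR-int (1.76), DNA-2-8_DR (1.62), Gypsy-22-LTR_DR (1.61) and Gypsy-24-LTR_DR (1.44). No group has 4 or more libraries, so no library was tested for standing apart from its group.

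The genotype ratios of early and late oocytes went together across families (Pearson r 0.827). Those of whole ovary followed them only weakly (0.139 with early and 0.0959 with late oocytes). The tables argue against the lower depth of the ovary libraries as the whole cause, since oocyte libraries thinned to 3892173 and 1302475 reads still had an r of 0.803, and against 1 genotype effect of equal size in all 3 materials as the whole of these ratios, since the slope of the ovary ratio on the mean oocyte ratio was 0.167 (bootstrap interval over families 0.0422 to 0.296). Whether fish or stocks with different transposon copies gave the oocyte and the ovary libraries of 1 genotype stays open. Of 15 copies at least 16-fold apart in both oocyte pairs, 86.7% (13) had, in the ovary of the genotype with the low oocyte level, at least 4 times that level, but the copies were chosen for that low level, which raises this share by itself. This cannot be told apart from cells other than oocytes in whole ovary, the separate table of ovary libraries or a material-dependent effect of tdrd6a. Each material has its own libraries. The shorter read limit of the ovary table is argued against as the whole cause. Each length from 36 to 39 nt held at most 0.0438% of reads in any oocyte library.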

How the results depend on the processing

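The count of 0 families for genotype held in 15 of the 16 alternatives, 1 of which was the negative binomial test and the others limma fits. In the limma fit as reported, 201 families had an unadjusted p under 0.05. The exception was the fit without the whole ovary pair, and leaving out 1 pair gave between 0 and 225 families. Named families kept their direction and side of the threshold in 149 of 160 genotype values. The 10 that changed side all passed without the whole ovary pair, and Gypsy100-I_DR-int reversed on sense reads (log2 0.24). For stage, 0 families passed in all alternatives, the negative binomial test among them, with 24 at an unadjusted p under 0.05 in the limma fit as reported. Of 130 named stage values, 128 kept direction and side, while hAT-N32_DR reversed on antisense reads (0.14) and DNA-6-N7_DR among reads of 24 to 32 nt (0.034). Genotype lists past the threshold numbered 2, with 1 on antisense reads, 3 on sense reads, 1 without the family that changed most in each list, 0 with an estimated correlation, and between 1 and 3 when 1 pair was left out. The LINE L1 list was not among the 3 on sense reads or the 3 without the whole ovary pair, so other lists passed there. Stage lists numbered 4, with 2 without a filter (Ngaro and Pao), 6 on antisense reads (Ngaro, Pao and Copia with Gypsy, PiggyBac and hAT) and 0 with an estimated correlation. On sense reads the stage lists past the threshold were 2 others, LTR Gypsy and LINE L2. For the interaction with whole ovary, 102 families became 213 with total-count scaling, 217 on antisense reads, 192 on sense reads, 162 with a pseudocount of 10 CPM, 44 with voom weights and 49 with the negative binomial test, all 49 among the 102. For strand balance, 3 families became 9 among reads of 24 to 32 nt and between 0 and 66 when 1 pair was left out. Whole ovary against oocytes stayed between 277 and 335 families. For each of these changes the cause was not tested, except that a fit with 1 pair fewer has fewer libraries.

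Without the most abundant family of each class, the mutant minus heterozygote shares of LTR, LINE and DNA reads were −2.04, 0.355 and 1.69 percentage points in early oocytes and −1.95, 0.680 and 1.33 in late oocytes. The antisense difference taken as the median over families of at least 100 reads was −2.52, −0.374 and −0.675 points in early oocytes, late oocytes and whole ovary, and the median change of the 750 families was −1.51, −0.524 and −1.07. Without LTR1_DR the mean length differed by −0.0700 nt in early oocytes. All of these kept their direction. Each ratio named within a material was also taken with median-ratio and with total-count scaling. All 20 of these values in early and all 20 in late oocytes moved by less than their counting interval. In whole ovary 8 of 20 values moved by more, and the ovary libraries had the most unequal scaling factors (1.08 and 0.968). Depth limits the mutant ovary most, where the floor was 2.30 CPM.

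A negative binomial test of the tallied reads called 0 families for genotype and 0 for stage, with 206 and 32 at an unadjusted p under 0.05. The planned edgeR and DESeq2 tests were not run, nor were library sizes from transposon classes alone, since the table holds no other class. Weights by number of hits and distinct sequences could not be had, and leaving out a genotype leaves no degree of freedom for stage. The genotype fit is paired by material, and pairing by replicate number was not possible because each group has a single library, numbered 1. Without the material term the genotype fit still called 0 families and 2 lists, while families at an unadjusted p under 0.05 went from 201 to 77 and the smallest adjusted p from 0.111 to 0.455. The added settings were chosen after seeing the data.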

Other observations

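The comparison of whole ovary with oocytes, the copies, and the tests on SINE2-1_DR length and on the splits for families and lists were chosen after the results were seen, and the other tests were fixed before. Whole ovary and oocytes differed in the level of many families, although each library held between 954 and 959 of the 960 families, and whole ovary was not selected by size as the oocytes were. In limma with Benjamini-Hochberg adjustment, 312 of 953 families passed, 142 higher and 170 lower in whole ovary. Gypsy-30-I_DR-int rose most in whole ovary, 28.9-fold in the heterozygote and 37.4-fold in the mutant over the mean of the oocyte libraries (log2 5.04 ± 0.16, SE, adjusted p = 0.000724), from 14.7 CPM in heterozygote early oocytes to 435 in heterozygote ovary. Gypsy-21-I_DR-int (3.41 ± 0.19), Gypsy83-I_DR-int (2.82 ± 0.12), Gypsy136-I_DR-int (2.79 ± 0.14) and the foamy virus-like ERV1-2-I_DR-int (2.69 ± 0.09) also rose. Gypsy75-I_DR-int (−5.47 ± 0.61), Copia-9-LTR_DR (−3.68 ± 0.38) and SINE2-1_DR (−2.32 ± 0.12) fell in whole ovary. The oocyte and ovary libraries stand in separate tables, which cannot be told apart from the material. The different read limits of these tables are argued against as the whole cause. Among reads of 24 to 32 nt, 279 families passed in limma, 127 higher and 152 lower in whole ovary.

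By list, Ngaro elements fell in whole ovary: 10 of 16 families passed, and all 16 were lower in both genotypes, against 367 of all 953 families. The Ngaro list was at 0.673 and 0.703 of its oocyte level (camera adjusted p = 6.31e-05, and an adjusted p of 0.834 with an estimated correlation). LTR Gypsy fell on balance, with 47 families that rose and 103 that fell of 315 (adjusted p = 0.00780), and En-Spm elements rose, with 7 of 29 families higher (adjusted p = 0.0222). With an estimated correlation the adjusted p was 0.801 for Gypsy and for En-Spm in the ovary comparison. On sense reads Ngaro was higher in whole ovary (adjusted p = 0.0277), and on antisense reads neither Gypsy (0.403) nor En-Spm (0.148) passed. Among reads of 24 to 32 nt Ngaro passed in the ovary comparison (0.000112), while Gypsy and En-Spm did not (0.0529 each). Adjusted over the list alone, 163 Gypsy, 13 Ngaro and 13 En-Spm families passed.

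Single copies, placed on Zv9 and uncertain because the treatment of reads that map to several places is not given, showed the largest contrasts. Of 8764 copies with a mean of at least 20 CPM, 394 differed by more than 2-fold in the same direction in both oocyte pairs, where independent lists would share 23.1, and 2 in opposite directions. In early oocytes and whole ovary, 90 did so in the same direction (36.3 for independent lists) and 59 in opposite directions. The number of opposite copies for independent lists was not computed, so the 90 by themselves do not show agreement in direction. A DNA-5-8_DR copy on chromosome 4 from 53541250 to 53541595 had 17 heterozygote and 4699 mutant reads in early oocytes, 10 and 2694 in late oocytes, and 3098 and 1226 in whole ovary. A Gypsy85-I_DR-int copy on chromosome 1 from 27413133 to 27419817 had 127 and 5872, 95 and 4708, and 109 and 4 reads. A BEL17-I_DR-int copy on chromosome 25 from 19277348 to 19283121 had 2596 and 32, 2212 and 52, and 426 and 186. The ERV1_DR-I-int copy on chromosome 9 from 20060818 to 20068778 had 5700 and 27571, 4662 and 17860, and 6046 and 150 reads. The 15 copies over 16-fold apart in both oocyte pairs lie at 10 loci when copies within 10 kb are joined, with 4 of them on chromosome 4 between 53538324 and 53543445 and 5 being parts of BEL17. None of the 15 was so in whole ovary in the same direction.

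The antisense share of transposon reads was lower in the mutant library of each pair. RNA fragments outside the piRNA length range are argued against as its cause, since between 96.6% and 101% of the difference was kept among reads of 24 to 32 nt. A change in which families are abundant is argued against as the whole cause, since between 51.9% and 56.0% of the difference was kept with family shares held at the mean of the pair, and the rest may come from such a change. Whether the shift is common to most families stays open, since between 55.7% and 65.9% of the 750 families were lower in the mutant, depending on the pair. An effect of the tdrd6a mutation on the loading of antisense piRNAs is a hypothesis that these libraries of total RNA do not test.

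SINE2-1_DR reads were higher in late than in early oocytes in both genotypes, without passing the test over the families. Fragments of tRNA outside 24 to 32 nt are argued against as the cause. Among reads of 24 to 32 nt the late over early ratio was 2.07 in the mutant and 2.67 in the heterozygote. These lengths made up at least 92.2% of the family's reads in every oocyte library. Length cannot tell tRNA fragments within this range from piRNAs. Orientation, for which no prediction had been fixed, argues against tRNA fragments as the main source of the rise. Such fragments would be sense to an element annotated in the direction of its tRNA. Between 92.3% and 96.0% of the family's oocyte reads were antisense, with 92.7% in late heterozygote and 96.0% in late mutant oocytes. Reads at 1 genomic copy are argued against as well, since the copy with the largest share carried 5.70% of the increase in the heterozygote and 12.5% in the mutant, out of 3225 copies with reads. A smaller contribution of tRNA fragments of 24 to 32 nt, other processing steps and an effect of the stage itself stay open, with 1 library for each stage and genotype.

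The 6 libraries can be split 3 against 3 in 10 ways, so the share of splits with a result as large is never under 0.1. Only 4 of the 10 part the pair of every material as the real split does, and among these the share is never under 0.25. The other 6 part the pair of 1 material only. With material as a block, their fits compare mutant with heterozygote in that material alone. Splits that part the same pair then give the same result, and these 6 are no regrouping of the genotypes. For genotype, 0 families passed in the real split and up to 2 in another, which also parts every pair. With a real count of 0 all 10 splits give as many by definition, so their number tests nothing. For lists, 2 passed in the real split, as many or more in 4 splits. The highest was 2 in the other splits that part every pair. It was 4 in the splits that part only the late oocyte pair, which hold the genotype difference of late oocytes. For strand balance, 3 families passed in the real split and 0 in every other, so 1 split, the real one, gave as many.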
